A study of Rattus norvegicus with 6 samples.

How the data were processed

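Gene expression was measured on 6 arrays, each with total RNA from rat soleus, a postural muscle of the lower hind limb made up mainly of slow fibres. Per the labels, the animals were young female Wistar rats, free of pathogens, the RNA was purified from frozen sections with a column kit, and 5 µg went onto each array. The labels describe every sample alike, as an age control at 14 days, and no other kind of sample was used here. The 6 samples therefore form a single group, and no contrast between conditions could be made. Replicates were numbered 1 to 6 in the order of deposit, so the numbers are names only. The labels do not say whether each sample came from a separate animal, so the spread between these samples may be partly technical. P-values for a difference between arrays rest on that spread. P-values for variability set the spread of a spot against that of the other spots, and say nothing about animals in general.

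The authors deposited a table of whole-number spot intensities, with 1185 spots in rows and the 6 arrays in columns. The array type, the number of colours, the scanner software, the background correction and any scaling are not given in the sources used here. From the values, the deposited intensities were linear. Replicates 1, 2, 3, 5 and 6 held 204 to 402 values at or below 0 each, so a background had been subtracted from them. Replicate 4 held no value under 67. Array medians were 1284, 1207, 785, 116, 1097 and 319 for replicates 1 to 6, an 11.1-fold difference between the highest and the lowest, so the columns were not on a common scale. The unit of the intensities is arbitrary and its scale factor is unknown. Intensities of different spots were ordered only to describe background and precision, and are not read as relative amounts of transcripts.

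The spot identifiers came in 2 series, 702 beginning with R and 483 beginning with RG. The file does not pair them with genes, and 0 of the 1185 matched an identifier, symbol or synonym in the rat RefSeq gene table of assembly GRCr8. No gene is therefore named. The 19 gene lists fixed before the data were examined (13 of pathways and 6 of cell type markers) had no assignable member. For this reason the tests of list variability and list coherence, the 4 relations between list scores and the set test of the title forms were not run. The rule for named genes, also fixed in advance, allowed only spots with a gene symbol. In its place 4 spots are given by identifier: the 2 with the highest ratio of variance to the level trend, and the 2 with the smallest SD among spots with a mean level above the median.

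Spots above 0 on all 6 arrays were kept (588 of 1185), their intensities were converted to log2 and the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Agreement was described by Pearson and Spearman correlations across spots for the 15 pairs of arrays; spots are not independent replicates. Spread was described by the SD over the 6 arrays and by the fold range, the highest over the lowest array. To find spots that varied more than others of like level, each spot's variance was divided by the value of a trend of variance on mean level fitted by limma, and the ratio was tested with an upper-tail F-test and Benjamini-Hochberg adjustment at 0.05. Sample titles come in 2 forms, a hash sign with a number for replicates 1 and 2, and the letters MF with a number for replicates 3 to 6. The labels do not say what the forms mean, so they were compared with limma only as a check for a technical or animal series. The precision of all values is limited by the number of arrays.

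Both tests were tested on simulated data with the means, the variance trend and the size (588 spots) of the real data. Over 100 simulations the fitted prior degrees of freedom had a median of 5.62, where 5.83 had been simulated. The spread test called 0% of spots with 1 array shifted 16-fold, 0.5% of those shifted 64-fold and 19% of those shifted 1024-fold. The comparison of title forms called 43.8% of spots shifted 4-fold and 89.2% of those shifted 16-fold, in 20 simulations with 60 shifted spots each.

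Alternatives fixed before the data were examined were scaling by the array median, no scaling, leaving out the dimmest 25% of spots, keeping all spots with values at or below 0 set to the lowest positive value, adding each array's 10th percentile of positive values before log2, other forms of the prior variance, and leaving out each array. Subtracting an estimated offset from replicate 4, leaving out replicates 4 and 6 together, and leaving out replicate 4 with median scaling or none, were chosen after seeing the data.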

Results

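The data set held 6 arrays of rat soleus muscle, all from samples labelled as age controls at 14 days. With a single group, the measurements describe the level of each spot in control soleus, how well the samples agreed, and which spots differed between samples that the labels describe alike. Because the spots carry identifiers without gene names, values are given by spot identifier.

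The arrays differed in overall signal. Total spot intensity was 13436430, 16519200, 16307855, 350826, 19251624 and 13334909 arbitrary units on replicates 1 to 6. Replicates 1, 2, 3 and 5 had median intensities between 785 and 1284 units and held 204 to 271 values at or below 0 among 1185 spots. Replicate 6 had a lower median of 319 units and 402 such values, 33.9% of its spots. Replicate 4 had a median of 116 units and a range of 67 to 37073, with 0 values at or below 0. Its intensities took only 312 distinct values, against 1040 to 1119 on the other arrays. The absolute values of replicate 4 were thus on another scale than those of the other 5 arrays, and agreement and spread are given from normalized values unless stated otherwise.

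**Figure D1:**
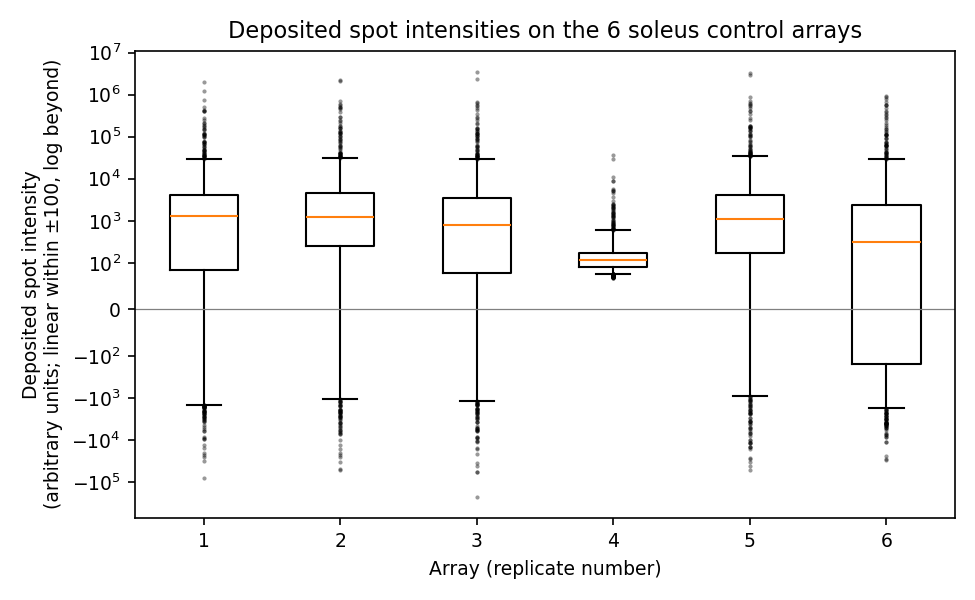
Deposited spot intensities (vertical axis, arbitrary units, linear within ±100 and logarithmic beyond) for the 1185 spots of each of the 6 arrays (horizontal axis, replicate number). Boxes span the quartiles with the median as a line, whiskers reach the 5th and 95th percentiles and points lie outside them. Replicate 4 has a median of 116 and no value at or below 0, and replicate 6 has the lowest median, 319, of the other 5.

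Many spots were above 0 on array after array, and some never were. A value just above 0 need not be signal. On the 5 arrays with a subtracted background, 588 spots (49.6%) were above 0 on all 5, where 326 would be if the arrays were independent. The independence figure gives every spot the same rate, so the excess shows only that spots differed from one another. A further 233 were above 0 on 4 arrays, 144 on 3, 101 on 2 and 71 on 1. On none of the 5 arrays were 48 spots (4.05%) above 0, against 0.722 under independence. All 48 were negative on every one of these arrays. Their deposited values also ranked alike from array to array, with Spearman correlations across the 48 spots between 0.43 and 0.88 for pairs of the 5 arrays.

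On replicate 4, the spots negative elsewhere were not the dimmest. The median on replicate 4 was 139 units for the 48 spots that were above 0 on no other array, 89 units for spots above 0 on 2 or on 3 of the others, and 146.5 units for the 588 above 0 on all 5. Of the 48, 17 lay above the upper quartile of replicate 4. Across the 48 spots, the intensity on replicate 4 was negatively correlated with that on each other array, with Spearman rho from -0.87 to -0.54. Over the 147 spots with a median above 10000 units on the other arrays, that median was 79.1 times the replicate 4 value less 89 units, with quartiles of 67.5 and 93.3.

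**Figure D2:**
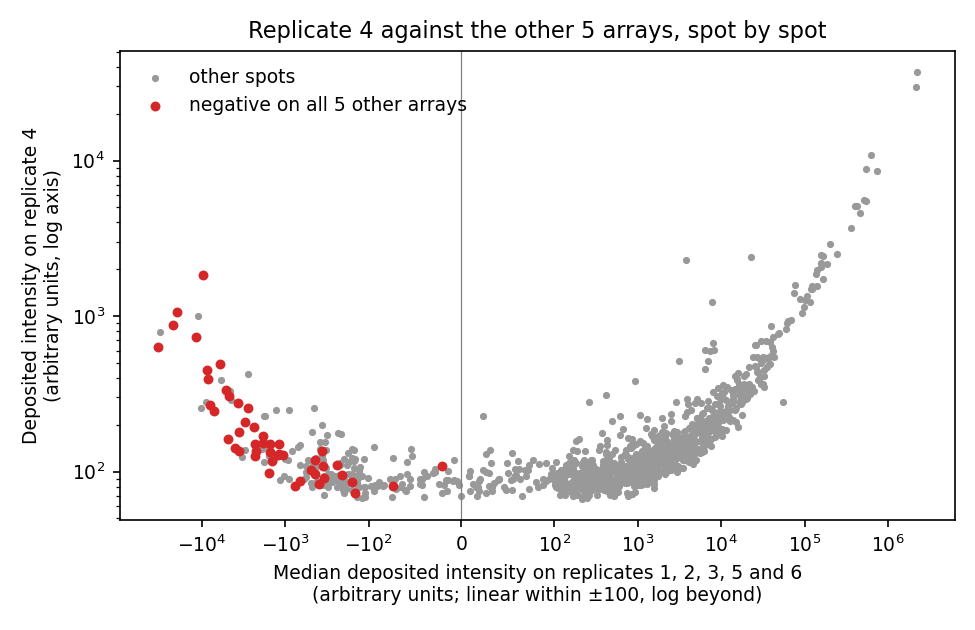
Deposited intensity of each of 1185 spots on replicate 4 (vertical axis, arbitrary units, log axis) against its median on the other 5 arrays (horizontal axis, arbitrary units, linear within ±100 and logarithmic beyond). Red points are the 48 spots negative on all 5 other arrays; their replicate 4 values have a median of 139 and increase as the other arrays become more negative.

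After quantile normalization of the 588 spots above 0 on all 6 arrays, the samples agreed to differing degrees. Pearson correlations of log2 intensity across spots had a median of 0.85 over the 15 pairs of arrays. The best agreement was between replicates 2 and 5 (r = 0.92), where 85.0% of spots lay within 2-fold of each other. The poorest was between replicates 1 and 6 (r = 0.70), where 45.6% did. The 5 pairs that include replicate 6 gave r between 0.70 and 0.83, and the 10 pairs without it gave 0.83 to 0.92. Spearman correlations on these spots ran from 0.62 to 0.95. The order of the arrays was not the same when the spots removed by the filter were included. Spearman correlations over all spots were 0.51 to 0.63 for the 5 pairs that include replicate 4. They were 0.62 to 0.79 for replicate 6 with replicates 1, 2, 3 and 5, so the ranges overlapped slightly. Replicate 6 thus agreed least on the 588 spots, and replicate 4 tended to agree least on all spots. No pair of arrays held identical values.

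On quantile-normalized values, the spread between samples was wide and narrowed with signal. The median SD over the 6 samples was 0.66 on the log2 scale, with quartiles of 0.46 and 0.96, and the highest and lowest samples of a spot were a median of 3.52-fold apart. They were at least 2-fold apart for 489 spots (83.2%) and at least 10-fold apart for 81 (13.8%). In the dimmest 25% of the 588 spots (147 spots) the median SD was 1.03, and in the brightest 25% it was 0.43. A range of 2-fold or more was seen in 96.6% of the dimmest and 59.2% of the brightest of these sets. With values scaled by the array median instead, the median SD was 0.86 and 95.2% of spots had such a range. The change of spread with level was not examined under that scaling.

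No spot was called as varying between samples beyond the level trend. In limma, at an adjusted p of 0.05, 0 of 588 spots passed, and 33 had an unadjusted value under 0.05 where 29.4 would by chance. The trend and its prior were fitted to the variances of these same 588 spots, so a count near chance is largely built in. That count does not show that the spots varied alike. In simulations of this design the test called 0.5% of spots with 1 array shifted 64-fold, so shifts of that size in a single sample would seldom have been called. The 2 spots with the highest ratio of variance to trend were RG138 and R326, each with an adjusted p of 0.136 in limma. RG138 had a normalized level of 15.39 ± 2.19 (log2, SD, n = 6), where the trend gave an SD of 0.42, and its samples spanned 77.4-fold. Its lowest value, 11.25, was on replicate 6, and the other samples lay between 15.17 and 17.52. R326 had a level of 11.26 ± 3.15 (log2, SD, n = 6) against a trend SD of 0.61. Its value was 5.35 on replicate 6 and between 10.82 and 14.54 on the others. The deposited intensity of R326 on replicate 6 was 20 units, on an array where 402 values were at or below 0, so that value cannot be told from background and its exact log2 level and SD carry no weight. With a pseudocount the SD was 2.27. Without replicate 6 the SD was 0.89 for RG138 and 1.27 for R326, so both rested largely on that array. R326 passed after scaling by the array median (SD 3.53, limma adjusted p = 0.00963), with the near-background value included. With the same scaling but without replicate 4 its SD was 3.92 and it did not pass (limma adjusted p = 0.37).

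The 2 least variable spots with a mean level above the median, by quantile-normalized values, were R656 and RG019. R656 had a level of 16.03 ± 0.11 (log2, SD, n = 6) and a range of 1.21-fold. RG019 had a level of 17.94 ± 0.14 (log2, SD, n = 6) and a range of 1.28-fold; without replicate 5 its SD was 0.03. The size of this spread depended on the scaling. With scaling by the array median, which leaves each array's own spread of values in place, their SDs were 0.83 and 0.96. The median spot had an SD of 0.86 there, so neither spot stood out as steady under that scaling. With the same scaling and without replicate 4, their SDs were 0.51 for R656 and 0.51 for RG019, where the median spot had 0.81. In the deposited values without replicate 4 they were 0.21 and 0.28, where the median spot had an SD of 0.79.

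**Figure D3:**
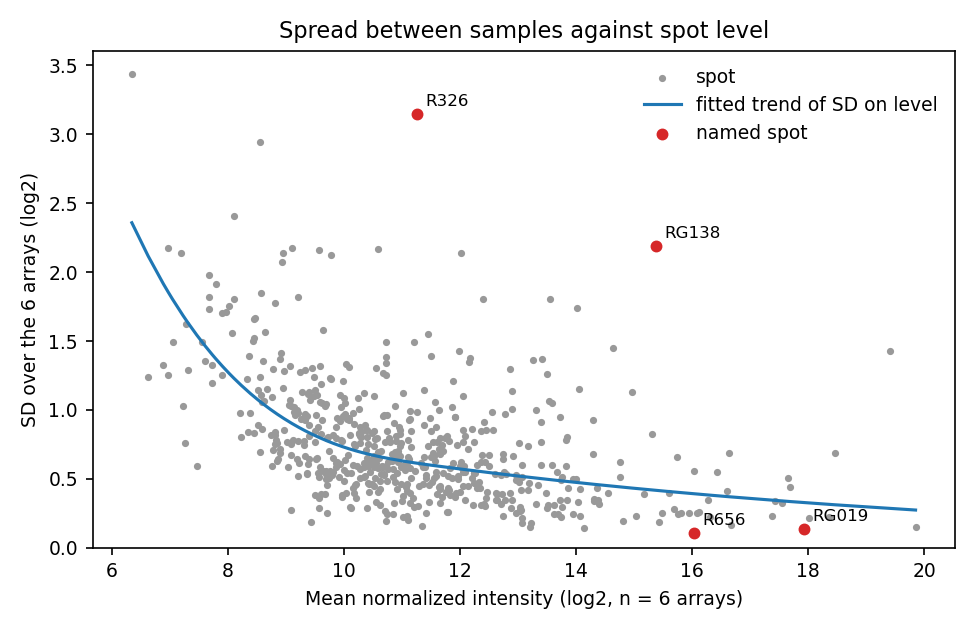
SD over the 6 arrays (vertical axis, log2) against mean normalized intensity (horizontal axis, log2, n = 6 arrays) for 588 spots, with the fitted trend as a line and the 4 named spots in red. The spread falls with level, from a median SD of 1.03 in the dimmest 25% to 0.43 in the brightest 25%, and R326 and RG138 lie far above the trend.

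No spot was called between the title forms with all 6 arrays kept, and 1 was called without replicate 6. Runs that left a single array titled with a hash sign are not part of that count of calls. Between the 2 samples titled with a hash sign and the 4 titled MF, 0 of 588 spots passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.325. At an unadjusted value under 0.05 there were 73 spots, 39 higher and 34 lower in the samples titled with a hash sign, where 29.4 would be expected by chance. The count was not stable: it was 50 with scaling by the array median and 9 with the values as deposited. It was 20 without replicate 1 and 97 without replicate 2, each of which leaves a single array titled with a hash sign that is assumed to vary like the others. With replicate 4 left out, chosen after seeing the data, the count was 53 with scaling by the array median and 31 with the deposited values. The median difference over all 588 spots on the 6 arrays was -0.08 (log2, hash sign minus MF). Quantile normalization gives every array the same set of values, so a median near 0 is largely built in and does not compare overall signal.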

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

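The tests of replicates 4 and 6 in this part were chosen after the values had been seen. With Dixon's test at 95%, chance flags about 1 in 20 normally distributed quantities that were not chosen for their spread. The test was applied to 9 quantities over the 6 arrays. It set apart the total intensity of replicate 4 (350826 units, the next lowest being 13334909), the normalized level of RG138 on replicate 6 (11.25, the next 15.17) and that of RG019 on replicate 5 (18.21, the next 17.90). RG138 had been picked for its high variance, so its flag restates that choice, and its gap over range barely reached the critical value. RG019 spanned only 1.28-fold in all, and its values on the other arrays were set by neighbouring ranks.

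Replicate 4 stood apart in scale and in having 0 values at or below 0. A lower scale alone, from less RNA or label with the same processing, would have left such values in place, and the fewest on any other array was 204, which argues against scale as the whole cause. If the local background had been left in the deposited values of this array only, the spots that were negative elsewhere should be bright on it. Over the 48 spots negative on all 5 other arrays, the median Spearman correlation of replicate 4 with the others was -0.80, consistent with that explanation. The background may then have been over-subtracted around those spots on the other arrays, which was not tested because the layout of the array is not known here. No biological explanation was tested, as the labels describe the samples alike.

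Replicate 6, and to a lesser extent replicate 1, held most of the values that stood alone. Applied to each of the 588 spots, Dixon's test set apart 55 lone low and 24 lone high values (79 in all, 13.4% of spots). Chance gives about 5% where values are normal and vary alike on every array. Log2 values near background need not meet that, so the excess does not by itself mark aberrant values. Replicate 6 held 25 of the low and 14 of the high values, and replicate 1 held 17 and 3. In the brightest 25%, 147 spots, replicate 6 was the lone low array 12 times, against 7 for replicate 1 and at most 1 for any other, and it was the lone high array 2 times. A lowering of the whole of replicate 6 by a common factor is removed by quantile normalization, so 12 against 7 cannot test it. A lower signal over background on that array may still account for part of this. Its median was 319 units and 402 of its values were at or below 0. Its total of 13334909 units, however, was close to the 13436430 of replicate 1. Spots lost singly on that array remain open too, since its lone lows in the brightest 25% outnumber its 2 lone highs. The balance was the other way for extremes that need not stand alone. Over all 588 spots, replicate 6 was the highest array for 198 and the lowest for 143, where equal shares would be 98. Replicate 1 was the lowest for 155 and the highest for 152. Quantile normalization gives every array the same set of values, so lows on some spots are offset by highs on others. The counts of highs and lows are therefore not separate evidence. A difference in the muscle sampled cannot be told apart from either explanation with 1 array per sample.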

How the results depend on the processing

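No paired analysis was possible because all samples belong to 1 group. The gene list tests were not run because no spot could be assigned a gene. The median r of 0.85 moved by less than the spread between pairs under each alternative but 1, falling to 0.68 when all 1185 spots were kept with values at or below 0 at the lowest positive value; a shift of a whole array leaves r as it is, so median scaling and the deposited values gave one value (0.83). The spread depended on the processing: the median SD, 0.66 (log2), was 0.86 with median scaling, 2.07 as deposited, 0.59 without the dimmest 25%, 2.27 with all spots kept and 0.58 with a pseudocount. The share of spots with a 2-fold range, 83.2%, was 95.2%, 100% and 93.2% with median scaling, as deposited and with all spots kept. A range tends to narrow with fewer arrays, so the shares below are not comparable with those above. Without replicate 4 the median SD was 0.79 as deposited (share 81.8%) and 0.81 with median scaling (88.4%). Normalized without replicates 4 and 6, it was 0.60 (66.1% of 705 spots). These settings were chosen after seeing the data. Leaving out 1 array gave a median SD of 0.58 (replicate 6) to 0.74 (replicate 4) and a share of 70.2% (replicate 6) to 82.6%. The count of spots varying beyond the trend was 0 in limma under all alternatives except median scaling, which called 1 (R326); the unadjusted count ran from 0 with a robust prior to 41 with all spots kept. The title forms gave a count of 0 under the alternatives run for it that kept every array (the robust prior was not), and the unadjusted count, 73, ran from 9 as deposited to 97 without replicate 2, with 20 without replicate 1 and 85 without replicate 6. Without replicate 1 or 2 the other stands alone and is assumed to vary like the MF arrays. Leaving out 1 of the MF arrays gave 0 calls, except for 1 without replicate 6 (R564, chosen after its values were seen, -2.08 log2, hash sign minus MF, limma adjusted p = 0.026). Without replicate 2, with replicate 1 alone, R676 and RG091 stood out, at -4.36 and -5.41 (log2, hash sign minus MF). The cause of these changes was not tested. Signal over background limits the dim spots: subtracting an offset of 89 units from replicate 4 left 538 of the 588 spots above 0 on all arrays.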

Other observations

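The comparison of title forms was set against all 15 splits of the 6 arrays into 2 and 4, a test planned before those counts were seen. The split by title gave 73 spots at an unadjusted p under 0.05 in limma, and the highest of the other splits, replicates 3 and 6 against the rest, gave 66. The 73 was not stable: other processing and leaving out 1 array gave 9 (as deposited) to 97 (without replicate 2, when replicate 1 alone is set against 4 arrays). Only 1 of the 15 splits, the one by title, gave as many, and 15 splits are too few for a share under 0.05. Splits that placed replicate 1 with 4, or replicate 4 with 6, gave 43 and 44 spots, and replicates 3 and 5 against the rest gave 4.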
